A study of Mus musculus with 70 samples.

How the data were processed

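The series holds bulk CEL-Seq2 libraries of mouse microglia sorted as CD11b+ CD45+ Ly6G- CD206- from perfused brains. Each library came from 500 cells in 30 uL of lysis buffer, of which 15 uL was used. Per the labels, read 1 carried a molecular identifier of 10 nt and a barcode of 9 nt, and read 2 an insert of 81 nt. There were 70 libraries in 17 groups, spread over 5 count tables: postnatal (19 libraries, Littman and Jung), BLZ-titled (15, both lines), vehicle and UC2288 (21, Littman), adult Jung (8) and adult Littman (7).

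The deposited values are whole-number counts per gene and library, without normalisation. They were taken as deduplicated molecules because the libraries carry molecular identifiers, though no header says so. The submitters' processing notes name UMI-tools, Trim Galore, HISAT2 and featureCounts on the mouse genome build GRCm38. Their versions, parameters, annotation release and strand setting are not given in the sources used here. Genes with near copies, such as MHC class I genes and ribosomal protein pseudogenes, may share reads, and how shared reads were counted is not given either. A 3' tag on Cx3cr1 may miss or include the knock-in transcript, so Cx3cr1 served as a check of the labels.

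Library totals ran from 329329 to 450461 counts in the postnatal table, 184513 to 236106 in the BLZ-titled table, 116083 to 277680 in the vehicle and UC2288 table, 274120 to 304794 for adult Jung and 288396 to 347941 for adult Littman. At this depth a gene at 20 CPM has only a few counts per library, so named genes needed a mean of at least 20 CPM in the higher group. All-zero genes numbered 178 in the vehicle and UC2288 table and 1068 in the adult Littman table. No count column was left out.

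Groups were taken from sample titles and labels. Cre- mice are Cx3cr1 wild type and all others carry 1 Cre allele; postnatal Jung and BLZ-titled Jung mice also carry Rosa26YFP. Per the labels, tamoxifen was 4 mg in adults, and 0.1 mg (P1 and P3) or 0.2 mg (P5 and P7) in pups. UC2288 and BLZ945 were given at 100 mg/kg, also per the labels. They place the postnatal, vehicle and UC2288 libraries in pups of P8 or P14, and the others in adults of 6 to 15 weeks. The treatment labels of adult Jung and BLZ-titled Jung libraries conflict with their titles; the titles defined the groups, and no comparison crossed them. The groups, comparisons, tests, gene lists, naming rule and most variations of the analysis were written down before the data were examined.

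Each table was fitted on its own with edgeR 4.0.16 in R 4.3.3: TMM size factors, filterByExpr by group, all groups of the table in 1 quasi-likelihood fit, Benjamini-Hochberg adjustment over tested genes, and a call at adjusted p below 0.05. The filter kept 7076 postnatal, 5163 BLZ-titled, 4953 vehicle and UC2288, 5111 adult Jung and 5512 adult Littman genes. Line differences and the UC2288 by Cre interaction were contrasts of the same fits. The adult tables do not hold the same genes, so the adult line difference was fitted on the 16013 genes in both (6256 tested); this join was chosen after seeing the data. It left out 1825 genes found only in the Jung and 2544 found only in the Littman table, none with more than 36 counts in sum. In that contrast the line is also the table, so an effect of table on oil and tamoxifen alike cancels, and any other does not.

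Named genes in each comparison were Cx3cr1 and Cdkn1a, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change (4 in difference tests) without predicted gene models, up to 4 called members per gene list, and all called genes where at most 5 were called. The text gives a selection of these, with repeats of genes named elsewhere. Among them, 2 genes are not reported here. Where a group had 0 counts in a comparison of 2 groups, the fold is a lower bound with 3 counts assumed over the group. Difference tests give the fitted value. With 1 to 3 counts, a ratio of pooled counts with its exact 95% interval replaced the fitted fold. That interval covers counting error only, not variation between libraries. CPM used TMM-scaled totals, and log2 CPM scores a prior count of 2.

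The 18 gene lists were p53 and DNA damage response, type I interferon response, homeostatic microglia, disease-associated microglia, cell cycle, inflammatory cytokines and NF-kB, antigen presentation, immediate early and dissociation, border macrophage, monocyte, neutrophil, lymphocyte, erythroid, neuron, astrocyte, oligodendrocyte lineage and endothelial markers, and mitochondrially encoded mRNAs. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for lists of at least 3 tested genes. The homeostatic list holds Cx3cr1, which the knock-in lowers, and the p53 list holds Cdkn1a. Genes of each list called by edgeR were counted over all genes and again with adjustment over the list alone, and list medians were repeated with genes of few counts at their bound.

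Variations fixed in advance were RLE size factors, no low-count filter, DESeq2 1.42.0, only the compared groups in the fit, the replicate number as a block, thinning to the smallest library, limma-voom with quality weights, leaving out each library, and the estimated camera correlation. Added after seeing the data were sex as a covariate (female above 20 Xist counts), leaving out libraries that stand apart from their group, and leaving out libraries with neutrophil or erythroid transcripts. Regroupings of the same libraries were counted as a test of chance, all splits where at most 56 exist and 100 drawn otherwise, the real one included. Draws used seed 20, and thinned and drawn counts depend on the draw. Within-group values were screened with Dixon's test.

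The procedure was tested on simulated data with 200 changed genes per comparison. Of genes changed 4-fold it recovered 95.5% in the postnatal comparisons, 93.9% in adult Littman, 92.4% in adult Jung, 87.9% in BLZ-titled Littman and 98.5% in BLZ-titled Jung. In the vehicle table it recovered 93.9% (Cre+ against Cre-), 87.9% (tamoxifen against oil) and 80.3% (oil Cre+ against Cre-), in the UC2288 comparisons 80.3% (Cre+), 77.3% (Cre-) and 81.8% (Cre+ against Cre-), and 56.1% in the interaction. The line differences recovered 83.3% (postnatal), 60.6% (BLZ-titled) and 62.1% (adult). Of genes changed 2-fold it recovered 71.6% in the postnatal comparisons, 52.2% in adult Littman, 56.7% in adult Jung, 22.4% in BLZ-titled Littman and 43.3% in BLZ-titled Jung. The vehicle comparisons recovered 29.9% (Cre+ against Cre-), 35.8% (tamoxifen against oil) and 26.9% (oil Cre+ against Cre-) of these, and the UC2288 comparisons 40.3% (Cre+), 26.9% (Cre-) and 25.4% (Cre+ against Cre-). The interaction recovered 7.46%, and the line differences 56.7% (postnatal), 14.9% (BLZ-titled) and 4.48% (adult). With 200 changed genes the Benjamini-Hochberg cutoff is easier to pass than where few genes change. All these shares may therefore be too high for comparisons with few or no calls. No pair of libraries was a repeat of the same counts. Reads were not realigned, and besides the 18 lists only the genes called higher and lower in the postnatal set were tested as sets. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.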

Results

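Cx3cr1CreERT2 mice carry a tamoxifen-dependent Cre recombinase in the Cx3cr1 locus, and 2 independently made lines, Littman and Jung, are in wide use for microglia. The 70 libraries each hold 3' transcript counts from 500 sorted microglia. Values below are normalised counts scaled to library size (CPM, mean ± SD) with log2 fold changes ± SE. Adjusted p-values are from edgeR quasi-likelihood tests with Benjamini-Hochberg correction over all tested genes. Gene lists were tested with limma camera at a preset correlation of 0.01, and each list call was repeated with the correlation estimated from the data. No label says that replicates are separate animals, and the pup age and tamoxifen schedule are not given per sample.

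To see how microglia with the Littman Cre differ from those without it after neonatal tamoxifen, 5 Cre+ libraries were compared with 5 Cre- libraries, all from tamoxifen-treated pups. This set has no Littman oil group. An effect of Cre with tamoxifen is therefore not separated from the replaced Cx3cr1 allele here. Cx3cr1, the fractalkine receptor gene that the knock-in replaces on 1 allele, was 2.70-fold lower in Cre+ (log2 fold change -1.43 ± 0.0706, 1510.1 ± 107.5 against 4071 ± 80.3 CPM, edgeR adjusted p 4.20e-21), which matches the genotypes in the labels. Cdkn1a, which encodes the p53-induced cell cycle inhibitor p21, rose 5.26-fold (log2 fold change 2.40 ± 0.182, 305 ± 94.1 against 57.8 ± 9.39 CPM, edgeR adjusted p 2.72e-14). Interferon-stimulated genes rose most: the DNA sensor gene Ifi204 by 18.2-fold (86.5 ± 21.5 against 4.38 ± 2.28 CPM), the antiviral gene Rsad2 by 11.2-fold (46.9 ± 17.5 against 3.98 ± 5.48) and Ifitm3, which blocks viral entry, by 10.1-fold (59.0 ± 20.7 against 5.57 ± 3.81). Oas2, which makes the activator of RNase L, had 117 counts in Cre+ and 3 in Cre- (ratio 35.7, exact 95% interval 11.9 to 176, counting error only).

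Genes outside the interferon list were called as well. The MHC class I heavy chain genes H2-K1 and H2-D1 rose 3.57-fold and 3.43-fold (1106 ± 119 against 309 ± 42.3 and 1149 ± 143 against 336 ± 44.5 CPM), and their light chain gene B2m rose 1.85-fold (6525 ± 343 against 3522 ± 235). Axl, a receptor that clears apoptotic cells, rose 8.99-fold (271 ± 76.8 against 30.1 ± 8.85 CPM, edgeR adjusted p 3.50e-15), and the lysozyme gene Lyz2 rose 3.06-fold (632 ± 133 against 206 ± 65.2). The monocyte chemokine gene Ccl12 rose 2.52-fold (309 ± 63.6 against 123 ± 24.3 CPM), and Ccl2 rose 7.33-fold with a wide spread (65.2 ± 77.6 against 8.34 ± 5.17). Cre+ replicate 2 had 202 CPM of Ccl2 and the other 4 had 15.4 to 49.99, and without it the log2 fold change fell from 2.88 to 1.84 (no low-count filter, edgeR adjusted p 0.00198). Bbc3, the p53 target that encodes the apoptosis inducer PUMA, rose 3.29-fold (30.1 ± 10.9 against 8.92 ± 2.54 CPM). The purinergic receptor gene P2ry12, a marker of resting microglia, fell 1.48-fold (log2 fold change -0.57 ± 0.0968, 3260.3 ± 793 against 4833 ± 535 CPM, edgeR adjusted p 3.67e-05), and the adhesion ligand gene Selplg fell 1.43-fold (2508 ± 431 against 3587 ± 293). The chromatin organiser gene Satb1 fell 3.94-fold (10.1 ± 3.78 against 40.7 ± 11.7 CPM) and the chemokine gene Ccl6 fell 2.53-fold (37.1 ± 10.3 against 94.9 ± 17.7).

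In all, edgeR called 552 of 7076 tested genes (323 higher, 229 lower), of which 73 rose and 56 fell at least 2-fold. Of 17 tested interferon genes, 16 were higher (16 when adjusted over the list alone, median log2 fold change 1.58, limma camera adjusted p 7.22e-38, and 2.32e-06 with estimated correlation). Antigen presentation genes were higher in 5 of 10 (6 over the list alone, limma camera adjusted p 1.79e-25, estimated 4.05e-06), and 14 of 21 homeostatic genes were lower and 1 higher (16 and 1 over the list alone, limma camera adjusted p 1.22e-19, estimated 0.00475). Disease-associated genes were called in both directions, 8 higher and 2 lower of 17 (10 and 4 over the list alone, limma camera adjusted p 3.84e-06, estimated 0.0361). Both p53 genes called (2 of 14, 6 over the list alone, limma camera adjusted p 0.00252, estimated 0.0319) and both inflammatory genes called (2 of 9, 2 over the list alone, limma camera adjusted p 0.00428, estimated 0.0319) were higher. The inflammatory list call was lost without Cre+ replicate 2 (limma camera adjusted p 0.0836, estimated 0.137), whose inflammatory score was 6.68 against 6.10 to 6.29 in the other 4. Cell cycle genes (2 of 24 higher, 3 over the list alone, limma camera adjusted p 0.00516) and mitochondrially encoded mRNAs (4 of 9 higher, 5 over the list alone, limma camera adjusted p 0.00252) lost their list calls with the estimated correlation (limma camera adjusted p 0.427 and 0.187). The calls of Mki67, Ccnb2, mt-Cytb and mt-Nd5 in them were lost in 6, 2, 4 and 2 of 10 fits that left out 1 library.

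Among marker lists of other cells in the same comparison, the 1 tested border macrophage gene, Mrc1, and the 1 tested monocyte gene, Plac8, were higher, while the 1 tested astrocyte gene, Slc1a3, and the 1 tested endothelial gene, Pecam1, were lower. Plac8 rose 4.94-fold (42.1 ± 22.1 against 8.50 ± 6.17 CPM), and Pecam1 fell 3.05-fold (9.86 ± 6.90 against 31.8 ± 7.29). Immediate early genes were higher in 1 of 5 (2 over the list alone, limma camera adjusted p 0.200), with Klf6 up 1.47-fold (312 ± 46.6 against 211 ± 32.8 CPM). Their score was 8.36 in Cre+ replicate 2 and 6.68 to 7.00 in the other 4, and without that library the list median went from 0.40 to -0.28 (log2), while Klf6 kept its call. The 3 oligodendrocyte genes and the 1 lymphocyte gene were not called, and no neutrophil, erythroid or neuron marker was abundant enough to test. As lists of 1, the monocyte and endothelial genes passed camera (limma camera adjusted p 0.00628 and 0.0102), and no correlation can be estimated for them. The calls for Mrc1 (log2 fold change 0.60) and Slc1a3 (-0.48) were lost when single libraries were left out, with edgeR adjusted p up to 0.271 and 0.171.

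**Figure D1:**
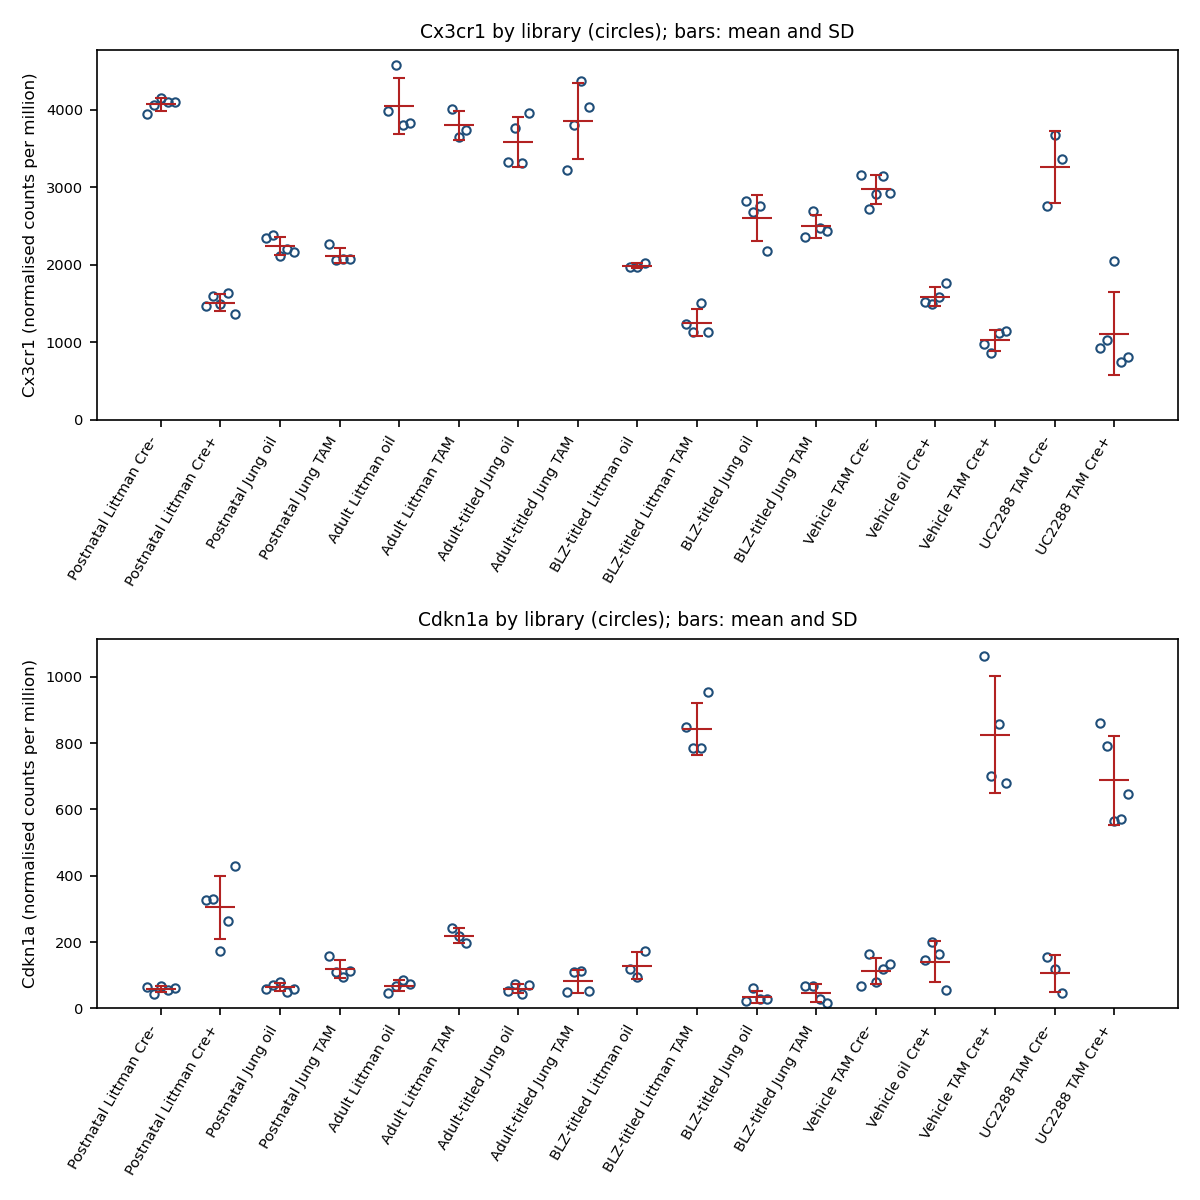
Cx3cr1 and Cdkn1a in every library. Circles are normalised CPM per library, and bars are mean and SD of each of the 17 groups.

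Whether tamoxifen alters microglia in pups of the Jung line was asked with 4 tamoxifen and 5 oil libraries, all heterozygous for Cre. H2-D1 rose 2.06-fold (log2 fold change 1.04 ± 0.119, 537 ± 83.3 against 259.7 ± 24.9 CPM, edgeR adjusted p 1.39e-07) and H2-K1 rose 1.70-fold (0.76 ± 0.123; 490.2 ± 96.3 against 288 ± 37.1, edgeR adjusted p 0.000449). B2m rose 1.28-fold (4222 ± 449.5 against 3302 ± 183 CPM), the nuclear body gene Sp100 rose 3.44-fold (49.8 ± 24.6 against 14.2 ± 3.59) and the ribosomal protein gene Rpl39 rose 1.43-fold (464 ± 38.6 against 324 ± 48.4). Cdkn1a was 1.87-fold higher without passing the test (log2 fold change 0.90 ± 0.224, 119 ± 26.9 against 63.6 ± 11.8 CPM, edgeR adjusted p 0.173), and Cx3cr1 was not called (2118 ± 97.4 against 2241 ± 115, edgeR adjusted p 0.972). edgeR called 6 of 7076 genes, all higher. Antigen presentation genes were higher in 3 of 10 (4 over the list alone, median log2 fold change 0.26, or 0.18 with low-count genes at their bound, limma camera adjusted p 1.01e-11, estimated 0.000679). No gene was called among 17 interferon, 21 homeostatic and 24 cell cycle genes (0, 0 and 7 over the list alone). Their list calls (limma camera adjusted p 0.000202, up, 0.000368, down, and 1.01e-11, up) were lost with the estimated correlation (limma camera adjusted p 0.0737, 0.251 and 0.112). Only H2-D1 and H2-K1 kept their calls whichever library was left out. Cdkn1a passed when the 2 Jung groups were fitted alone (edgeR adjusted p 0.00808) or without the low-count filter (0.00187).

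The line difference subtracts the Jung tamoxifen effect from the Littman Cre effect over 19 postnatal libraries, so it mixes line with the kind of control. Cdkn1a rose more in Littman, by a log2 difference of 1.49 ± 0.301 (edgeR adjusted p 0.00552), and so did Lyz2 (1.39 ± 0.239; 0.00122), H2-K1 (1.07 ± 0.165; 0.000168), Ccl12 (1.21 ± 0.254; 0.00888) and Ifitm3 (3.98 ± 0.817; 0.00701). The cathepsin gene Ctsb (0.62 ± 0.123) and the microglial gene Olfml3 (0.64 ± 0.114) were also higher, and the cell adhesion gene Sdk1 was lower (-1.63 ± 0.344). The Cx3cr1 difference of -1.35 ± 0.102 (edgeR adjusted p 1.07e-13) does not separate the replaced allele, which the Cre- controls of the Littman side lack, from an effect of tamoxifen. edgeR called 25 of 7076 genes (18 higher, 7 lower). Interferon genes (3 of 17 higher, 8 over the list alone, limma camera adjusted p 2.64e-14, estimated 0.000718) and antigen presentation genes (3 of 10 higher, 4 over the list alone, limma camera adjusted p 1.36e-06, estimated 0.00635) were higher in Littman. Homeostatic genes were lower as a list (1 higher and 1 lower of 21, 1 and 9 over the list alone, limma camera adjusted p 2.03e-11, estimated 0.0260). Disease-associated genes (3 of 17 higher, 8 higher and 2 lower over the list alone, limma camera adjusted p 9.22e-06) lost their list call with the estimated correlation (limma camera adjusted p 0.0510). Inflammatory genes (1 of 9 higher, 1 over the list alone, limma camera adjusted p 0.00127, estimated 0.0256) were higher, a list call that only the preset correlation kept without Littman Cre+ replicate 2 (limma camera adjusted p 0.0237, estimated 0.0590), and the endothelial gene Pecam1 was lower as a list of 1 (0.0151). Mitochondrial mRNAs (0 of 9, 0 over the list alone, limma camera adjusted p 0.0116) lost their list call with the estimated correlation (limma camera adjusted p 0.274). Ifi204, Axl, H2-D1, Mgll and Slc24a3 lost their calls without some single library.

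In adult Littman mice, 3 tamoxifen and 4 oil libraries were compared to ask whether tamoxifen alters adult microglia with this Cre. Cdkn1a rose 3.16-fold (log2 fold change 1.66 ± 0.235, 219 ± 22.0 against 68.9 ± 16.9 CPM, edgeR adjusted p 0.00905). Cx3cr1 (3798 ± 188 against 4046 ± 359 CPM, edgeR adjusted p 0.998) and H2-K1 (1.18-fold higher, 477 ± 22.1 against 405 ± 12.9; 0.998) were not called. In the simulation of this comparison only 5.97% of 1.5-fold changes were recovered. Cdkn1a was the 1 gene called by edgeR among 5512. The p53 list (1 of 10 higher, 1 over the list alone, limma camera adjusted p 0.00694) and the interferon list (0 of 7, 2 over the list alone, limma camera adjusted p 0.0378) lost their calls with the estimated correlation (limma camera adjusted p 0.144 and 0.174). With sex as a covariate Cdkn1a did not pass (log2 fold change 1.51, edgeR adjusted p 0.0641), and it did not pass when any of 4 single libraries was left out.

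For the libraries titled adult Jung, 4 tamoxifen and 4 oil libraries were compared. Their treatment labels name the CSF1R inhibitor BLZ945 while those of the libraries titled BLZ Jung do not, so these 2 sets may be exchanged. BLZ945 would then be mixed into the adult and the BLZ-titled line difference. Cdkn1a (81.5 ± 34.7 against 60.2 ± 15.0 CPM, edgeR adjusted p 1.000), Cx3cr1 (3857 ± 486 against 3588 ± 322) and H2-K1 (366 ± 58.9 against 341 ± 52.2) were not called. edgeR called 0 of 5111 genes, with 113 at an unadjusted p below 0.05; DESeq2 and voom called 0 and 0. No gene list passed. The adult line difference over 15 libraries had 0 edgeR calls among 6256 genes, with 174 below 0.05 unadjusted and 0 and 0 by DESeq2 and voom, so no difference was called for Cdkn1a (log2 difference 1.23 ± 0.400, edgeR adjusted p 1.000). Its interferon list (0 of 9, 1 over the list alone, limma camera adjusted p 0.0156) lost the call with the estimated correlation (limma camera adjusted p 0.0708).

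After BLZ945, which blocks the CSF1 receptor on which microglia depend, 4 tamoxifen and 3 oil libraries of the Littman line were compared. Cdkn1a rose 6.50-fold (log2 fold change 2.70 ± 0.270, 843 ± 79.0 against 129 ± 41.4 CPM, edgeR adjusted p 1.79e-07). H2-D1 rose 1.98-fold (4075 ± 621 against 2061 ± 367 CPM, edgeR adjusted p 0.0257) and the inhibitory receptor gene Cd300lf rose 5.76-fold (134 ± 79.8 against 22.6 ± 12.9, edgeR adjusted p 0.0248). Cx3cr1 was 1.59-fold lower without passing (1251 ± 174 against 1988 ± 30.3 CPM, edgeR adjusted p 0.186), but passed with DESeq2 (adjusted p 0.0303) and with limma-voom (0.0349). edgeR called these 3 of 5163 genes. All 3 oil libraries were male and 3 of 4 tamoxifen libraries were female by Xist counts. With sex as a covariate Cdkn1a passed (log2 fold change 2.91, edgeR adjusted p 5.35e-06), while H2-D1 (1.09; 0.128) and Cd300lf (1.90; 0.999) did not. The p53 list was higher (1 of 11 called, 2 over the list alone, median log2 fold change 0.75, limma camera adjusted p 1.87e-09, estimated 0.000294). No interferon gene of 25 was called (0 over the list alone). Homeostatic genes (0 of 20, 8 lower over the list alone, limma camera adjusted p 2.57e-08, down) and antigen presentation genes (1 of 11, 3 over the list alone, 0.000508, up) lost their list calls with the estimated correlation (limma camera adjusted p 0.198 and 0.198). The single astrocyte gene tested, Slc1a3, passed camera as a list of 1 (limma camera adjusted p 0.0295) and was not called on its own. Cdkn1a alone kept its call whichever library was left out.

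In the 4 tamoxifen and 4 oil libraries titled BLZ Jung, Cdkn1a (45.4 ± 27.0 against 35.8 ± 18.3 CPM, edgeR adjusted p 0.942), Cx3cr1 (2494 ± 145 against 2606 ± 294; 0.976) and H2-D1 (839 ± 94.96 against 716 ± 70.2; 0.890) were not called. edgeR called 0 of 5163 genes, with 287 at an unadjusted p below 0.05, and DESeq2 and voom called 0 and 0. The interferon list (0 of 25, 3 over the list alone, median log2 fold change 0.50, or 0.21 with low-count genes at their bound, limma camera adjusted p 0.000900, up) and the mitochondrial list (0 of 11, 0 over the list alone, 0.000238, up) lost their calls with the estimated correlation (limma camera adjusted p 0.496 and 0.496). Between the Littman and Jung libraries titled BLZ, 15 in all, the Cdkn1a effect differed by 2.40 ± 0.505 on the log2 scale, which did not pass (edgeR adjusted p 0.234) but passed with DESeq2 (adjusted p 0.0190) and limma-voom (0.0479). The labels of that Jung set name no BLZ945, so line and BLZ945 are not separated there. That difference had 0 edgeR calls of 5163, with 417 below 0.05 unadjusted and 1 and 1 by DESeq2 and voom. Its p53 (limma camera adjusted p 0.00645, up), interferon (0.00344, down), homeostatic (0.000145, down) and mitochondrial lists (0.0192, down) all lost their calls with the estimated correlation (limma camera adjusted p 0.0627, 0.430, 0.430 and 0.587).

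A further set of Littman libraries, from pups per the labels, paired tamoxifen with vehicle or with UC2288, a compound that lowers p21. To ask first what tamoxifen and Cre do under vehicle, 4 Cre+ libraries were compared with 5 Cre- libraries, both with tamoxifen. Cx3cr1 was 2.90-fold lower in Cre+ (log2 fold change -1.53 ± 0.215, 1026 ± 133 against 2972 ± 184 CPM, edgeR adjusted p 1.48e-06). Cdkn1a rose 7.26-fold (2.86 ± 0.271; 826 ± 177 against 113 ± 39.4, edgeR adjusted p 3.72e-10). The interferon-induced genes Ifi213 (189 counts, at least 59.5-fold), Ifi211 (155, at least 48.8-fold), Oasl1 (135, at least 42.5-fold) and Zbp1, a sensor of Z-form nucleic acid (119, at least 37.5-fold), had 0 counts in Cre-. Oasl2, which dampens nucleic acid sensing, rose 74.9-fold (499.8 ± 32.9 against 6.64 ± 9.56 CPM). H2-K1 rose 7.74-fold (1820.3 ± 416 against 234 ± 20.8 CPM), and Tap1, which loads peptides onto MHC class I, rose 3.94-fold (202 ± 24.4 against 51.2 ± 17.7). The chemokine genes Ccl2 and Ccl12 rose 18.2-fold and 6.39-fold (815 ± 135 against 45.2 ± 26.1 and 1202 ± 312 against 187 ± 61.5 CPM), and Nfkbia, the feedback inhibitor of NF-kB, rose 3.26-fold (347 ± 52.8 against 106 ± 30.5). The p53 targets Zmat3 and Ccng1 rose 8.66-fold and 2.72-fold (47.2 ± 12.1 against 4.52 ± 4.53 and 135 ± 23.6 against 49.4 ± 19.2).

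Of 20 homeostatic genes, 15 were lower and 2 higher in the same comparison, without a list call at the estimated correlation (limma camera adjusted p 0.0710). P2ry12 fell 4.25-fold (log2 fold change -2.09 ± 0.337, 895 ± 169 against 3811 ± 515 CPM, edgeR adjusted p 1.72e-05), the protease inhibitor gene Cst3 3.67-fold (3019 ± 218 against 11079.8 ± 2228) and the lipid receptor gene Gpr34 2.93-fold (484 ± 109 against 1428 ± 197). Trem2, the lipid-sensing receptor of disease-associated microglia, fell 2.46-fold (339.5 ± 26.9 against 833 ± 107.5 CPM), the lysosomal gene Cd68 2.37-fold (342 ± 33.5 against 812 ± 87.4) and the mannose receptor gene Mrc1 3.18-fold (114 ± 39.0 against 376 ± 70.9). The mitotic kinase gene Cdk1 fell 2.66-fold (83.1 ± 28.6 against 212 ± 27.6 CPM) and the mitochondrial gene mt-Nd4 2.29-fold (3827 ± 762 against 8767 ± 775). edgeR called 1347 of 4953 genes (710 higher, 637 lower), of which 495 rose and 348 fell at least 2-fold. Broad shifts went with these calls. The mitochondrial share of counts was 8.78 ± 0.823% in Cre+ against 13.8 ± 1.75% in Cre-. Ribosomal protein pseudogenes had a median log2 fold change of -1.21. A difference in RNA quality was not tested, so the lower genes cannot be assigned to Cre alone. All 28 interferon genes were higher (28 over the list alone, median log2 fold change 5.09, or 4.06 with low-count genes at their bound, limma camera adjusted p 7.23e-72, estimated 1.41e-05). Inflammatory (6 of 9, 6 over the list alone), antigen presentation (8 of 11, 9 over the list alone) and p53 genes (5 higher and 1 lower of 10, the same over the list alone) were higher as lists (limma camera adjusted p 4.21e-06, 2.35e-08 and 0.00866; estimated 0.0324 for each). Cell cycle genes (15 of 26 lower, 15 over the list alone, limma camera adjusted p 3.90e-07, estimated 0.0220) and all 10 mitochondrial mRNAs (10 over the list alone, 4.58e-08, estimated 0.0324) were lower. Homeostatic genes (15 lower and 2 higher of 20, the same over the list alone, limma camera adjusted p 2.49e-08) and disease-associated genes (9 lower and 2 higher of 16, the same over the list alone, 0.00866) lost their list calls with the estimated correlation (limma camera adjusted p 0.0710 and 0.0884).

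The 4 vehicle Cre+ tamoxifen libraries were then compared with 4 vehicle Cre+ oil libraries, which share the genotype, to ask whether tamoxifen is needed. Cdkn1a rose 5.80-fold (log2 fold change 2.54 ± 0.290, 826 ± 177 against 141 ± 61.3 CPM, edgeR adjusted p 3.20e-08). Ifi204 rose 57.2-fold (617 ± 10.8 against 11.3 ± 14.0 CPM), Oasl2 46.8-fold (499.8 ± 32.9 against 9.68 ± 4.97), and the RNA sensor gene Ifih1 had 114 counts against 0 (at least 25.6-fold). Cybb, which encodes the phagocyte oxidase subunit, had 410 counts against 1 (ratio 276, exact 95% interval 49.2 to 10921, counting error only). H2-K1 rose 7.79-fold (1820.3 ± 416 against 234 ± 25.4 CPM), Ccl2 22.0-fold (815 ± 135 against 35.6 ± 15.5) and Axl 13.0-fold (338 ± 83.9 against 25.4 ± 11.2). Mdm2, the p53 feedback inhibitor, rose 4.07-fold (85.6 ± 27.6 against 19.4 ± 4.10 CPM). P2ry12 fell 5.23-fold (895 ± 169 against 4687 ± 258 CPM) and the selenium carrier gene Selenop 10.9-fold (87.4 ± 22.3 against 938 ± 690.1). The microglial gene Crybb1 fell 6.07-fold (96.9 ± 23.0 against 598 ± 125.6) and the mitotic gene Ube2c 3.51-fold (45.9 ± 14.6 against 164 ± 71.4). Cx3cr1 fell 1.55-fold (1026 ± 133 against 1589 ± 124 CPM, edgeR adjusted p 0.0278), a call lost without the low-count filter (edgeR adjusted p 0.0525) and without any of 3 single libraries.

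That comparison had 1556 edgeR calls among 4953 genes (799 higher and 757 lower, with 608 and 465 at least 2-fold). The mitochondrial share of counts was 8.78 ± 0.823% with tamoxifen against 10.2 ± 1.49% with oil. Ribosomal protein pseudogenes had a median log2 fold change of -1.45, so RNA quality is not separated from tamoxifen here either. All 28 interferon genes were again higher (28 over the list alone, median log2 fold change 5.59, or 3.98 with low-count genes at their bound, limma camera adjusted p 1.04e-54, estimated 9.89e-05). Inflammatory (7 of 9 higher, 7 over the list alone, limma camera adjusted p 3.10e-07, estimated 0.0289), antigen presentation (8 of 11, 8 over the list alone, 3.10e-07, estimated 0.0348) and p53 genes (5 of 10 higher, 5 higher and 1 lower over the list alone, 0.00444, estimated 0.0289) were higher. Homeostatic genes (16 lower and 1 higher of 20, 18 and 2 over the list alone, limma camera adjusted p 2.23e-10, estimated 0.0368) and disease-associated genes (10 lower and 2 higher of 16, the same over the list alone, 0.00104, estimated 0.0368) were lower. So were cell cycle (12 of 26 lower, 13 over the list alone, limma camera adjusted p 1.19e-05, estimated 0.0289) and mitochondrial genes (10 of 10 lower, 10 over the list alone, 4.09e-08, estimated 0.0348). Both tested monocyte genes, Plac8 and Itgal, were higher in each vehicle tamoxifen comparison, as a list with limma camera adjusted p 0.000834 against Cre- and 0.00293 against oil. The border macrophage list split, with Siglec1 higher and Mrc1 lower, and the astrocyte gene Slc1a3 was higher, while the single lymphocyte, neuron and oligodendrocyte genes were not called.

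Without tamoxifen, the 4 Cre+ oil libraries were compared with the 5 Cre- tamoxifen libraries. Cdkn1a (141 ± 61.3 against 113 ± 39.4 CPM, edgeR adjusted p 0.924), H2-K1 (234 ± 25.4 against 234 ± 20.8, edgeR adjusted p 1.000) and Ccl2 (35.6 ± 15.5 against 45.2 ± 26.1) were not called. Cx3cr1 was 1.87-fold lower (log2 fold change -0.90 ± 0.211, 1589 ± 124 against 2972 ± 184 CPM), as 1 replaced allele would give, but did not pass (edgeR adjusted p 0.163). It passed when the 2 groups were fitted alone (edgeR adjusted p 6.47e-05) and with DESeq2 (0.0135). edgeR called 0 of 4953 genes, with 290 at an unadjusted p below 0.05, and DESeq2 and voom called 3 and 3. No interferon gene of 28 was called (1 lower over the list alone). The homeostatic (limma camera adjusted p 0.0114, up; 0 of 20 called, 1 higher and 1 lower over the list alone) and inflammatory lists (0.0133, down; 0 of 9 called, 1 lower over the list alone) lost their calls with the estimated correlation (limma camera adjusted p 0.450 and 0.450).

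**Figure D2:**
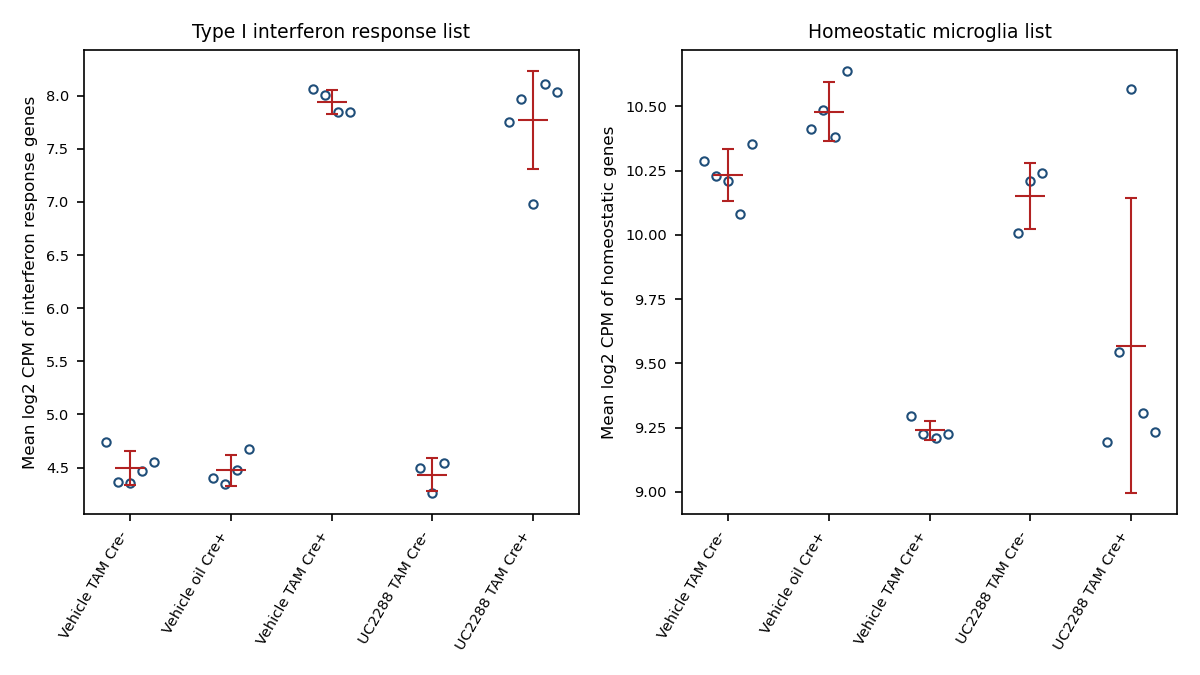
Interferon and homeostatic scores in the vehicle and UC2288 groups. Each point is the mean log2 CPM of the list in 1 library, with group mean ± SD.

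Whether UC2288 changes the tamoxifen response of Cre+ microglia was asked with 5 UC2288 and 4 vehicle libraries. Cdkn1a was not called (688 ± 133 against 826 ± 177 CPM; log2 fold change -0.26 ± 0.237, edgeR adjusted p 0.608), nor was Cx3cr1 (1111 ± 535 against 1026 ± 133, edgeR adjusted p 0.830). H2-K1 was not called either (1943 ± 1016 against 1820.3 ± 416 CPM, edgeR adjusted p 0.904). Wdr89, which encodes a WD-repeat protein, rose 9.66-fold (338 ± 264 against 33.4 ± 18.5 CPM, edgeR adjusted p 0.00418), and ribosomal protein pseudogenes such as Rpl10a-ps1 (2.56-fold; 597 ± 243 against 228 ± 78.3) and Rpl9-ps6 (2.76-fold; 497 ± 266 against 179 ± 40.8) rose as well. Cst3 rose 2.17-fold (6562 ± 4395 against 3019 ± 218 CPM, edgeR adjusted p 0.0462). The small RNA guide protein gene Ago3 fell 3.05-fold (36.9 ± 14.9 against 111 ± 20.9 CPM), and Suz12, a subunit of Polycomb repressive complex 2, fell 2.48-fold (50.8 ± 17.1 against 129 ± 38.2). edgeR called 36 of 4953 genes (32 higher, 4 lower). The count ran from 1 (without vehicle Cre+ replicate 3) to 266 (without UC2288 Cre+ replicate 1) when single libraries were left out, and 6 of 100 groupings reached 36. No interferon gene of 28 (2 lower over the list alone) and no p53 gene of 10 (0 over the list alone) was called. The homeostatic (1 of 20, 9 higher and 1 lower over the list alone, limma camera adjusted p 0.00254), mitochondrial (0 of 10, 4 over the list alone, 0.000157) and cell cycle lists (0 of 26, 0 over the list alone, 0.0278), all up, lost their calls with the estimated correlation (limma camera adjusted p 0.473, 0.461 and 0.461). Each of the 12 named genes lost its call when some single library was left out, and without replicate 3 of UC2288 Cre+ the Cst3 change shrank to a log2 fold change of 0.65 (edgeR adjusted p 0.147).

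In Cre- microglia, 3 UC2288 libraries were compared with 5 vehicle libraries. Pim1, a survival kinase gene, rose 5.54-fold (log2 fold change 2.47 ± 0.400, 104 ± 48.3 against 19.1 ± 5.01 CPM, edgeR adjusted p 0.00216). Cdkn1a (106.6 ± 55.7 against 113 ± 39.4 CPM, edgeR adjusted p 0.956) and Cx3cr1 (3265 ± 464 against 2972 ± 184; 0.863) were not called. Pim1 was the 1 gene that edgeR called among 4953, and the call was lost without UC2288 Cre- replicate 1, a library with neutrophil transcripts (log2 fold change 1.99, edgeR adjusted p 0.779). That library also stood apart on Fkbp5 (85 counts) and Ddit4 (56 counts). UC2288 Cre- replicates 2 and 3 had 3 and 6 counts of Fkbp5 and 3 and 1 of Ddit4. Vehicle Cre- libraries had 4 to 8 and 1 to 8. The source of this difference was not tested. The disease-associated (limma camera adjusted p 0.000959), cell cycle (0.00558) and mitochondrial lists (0.0122), all down with no gene called in them and 0 over each list alone, lost their calls with the estimated correlation (limma camera adjusted p 0.128, 0.220 and 0.591).

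The Cre effect under UC2288 was asked with the 5 Cre+ and 3 Cre- libraries. Cdkn1a rose 6.42-fold (log2 fold change 2.68 ± 0.327, 688 ± 133 against 106.6 ± 55.7 CPM, edgeR adjusted p 2.46e-07), and Cx3cr1 was 2.94-fold lower (1111 ± 535 against 3265 ± 464, edgeR adjusted p 3.65e-06). Ifitm3 rose 96.4-fold (1227 ± 643 against 11.1 ± 15.2 CPM) and Ifi204 57.4-fold (497 ± 167 against 7.01 ± 6.14). Ifit3 had 198 counts against 0 (at least 38.9-fold). Irf7, the amplifier of type I interferon, had 295 against 1 (ratio 174, exact 95% interval 31.0 to 6894, counting error only). H2-K1 rose 9.77-fold (1943 ± 1016 against 199 ± 32.3 CPM), B2m 3.69-fold (12308 ± 4457 against 3335 ± 1132), Axl 14.9-fold (339.6 ± 201 against 21.3 ± 21.0) and Ccl2 15.1-fold (649.9 ± 433 against 40.7 ± 19.4). Mrc1 fell 3.47-fold (141 ± 100.4 against 481 ± 177 CPM). edgeR called 198 of 4953 genes (174 higher, 24 lower; 164 and 20 at least 2-fold). All 28 interferon genes (28 over the list alone, median log2 fold change 4.72, or 3.71 with low-count genes at their bound, limma camera adjusted p 6.39e-117, estimated 7.46e-07) were higher. So were 6 of 9 inflammatory (7 over the list alone, limma camera adjusted p 9.03e-12, estimated 0.00369), 9 of 11 antigen presentation (10 over the list alone, 1.27e-20, estimated 0.00161) and 2 of 10 p53 genes (4 over the list alone, 0.000894, estimated 0.00856). Homeostatic (1 lower of 20, 3 over the list alone, limma camera adjusted p 1.23e-06), cell cycle (0 of 26, 0 over the list alone, 0.0188) and mitochondrial lists (0 of 10, 0 over the list alone, 0.0292), all down, lost their calls with the estimated correlation (limma camera adjusted p 0.129, 0.163 and 0.340). Both monocyte genes were higher (limma camera adjusted p 2.13e-05 as a list of 2). The Itgal call was lost when any of 4 single libraries was left out (edgeR adjusted p up to 0.113).

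The UC2288 by Cre interaction over 17 libraries tested whether the compound acts differently in the 2 genotypes. It was not called for Cdkn1a (log2 difference -0.18 ± 0.427, edgeR adjusted p 0.842) or Cx3cr1 (-0.02 ± 0.307; 0.984), and no interferon gene of 28 was called (0 over the list alone). Wdr89 was higher with UC2288 in Cre+ relative to Cre- (4.98 ± 0.787, edgeR adjusted p 0.00134), as was the mitotic kinase gene Cdk1 (1.54 ± 0.379; 0.0398), and Pim1 was lower (-2.91 ± 0.491; 0.00230). Under vehicle, Pim1 had 19 to 33 raw counts per library in Cre+ and 2 to 4 in Cre-. With UC2288 it had 4 to 27 in Cre+ and 8 to 33 in Cre-. The negative Pim1 value thus goes with its rise under UC2288 in Cre-, from a lower vehicle level than in Cre+. edgeR called 96 of 4953 genes (47 higher, 49 lower). Leaving out 1 library gave 1 (UC2288 Cre- replicate 1) to 533 (UC2288 Cre- replicate 3), and there were 2 without the libraries that stand apart. Wdr89 alone of 11 named genes kept its call whichever library was left out. The homeostatic (1 of 20, 6 higher and 1 lower over the list alone, limma camera adjusted p 0.02503), disease-associated (0 of 16, 6 over the list alone, 0.00202), cell cycle (2 of 26, 4 over the list alone, 0.00202) and mitochondrial lists (0 of 10, 5 over the list alone, 0.000130), all up, lost their calls with the estimated correlation (limma camera adjusted p 0.799, 0.160, 0.160 and 0.197).

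**Figure D3:**
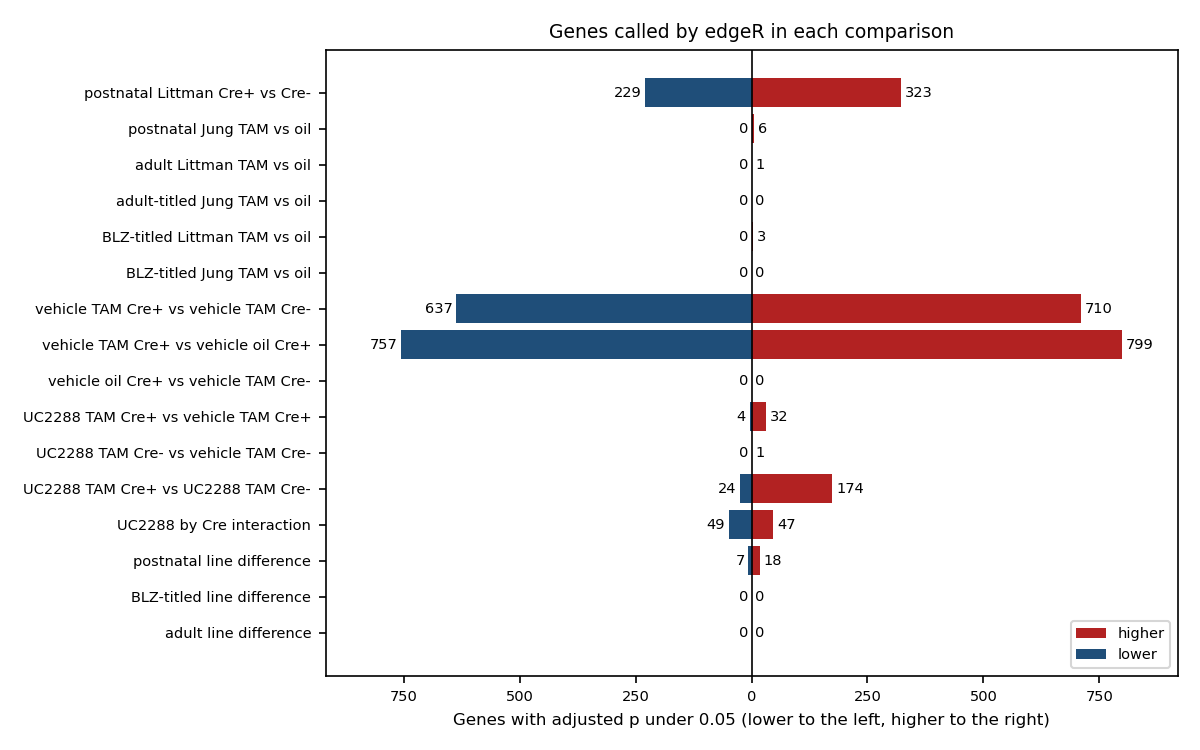
Genes called higher and lower by edgeR in each comparison.

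The postnatal and vehicle sets of Littman libraries were compared to see how far the Cre response recurs, over 4648 genes tested in both. Of the genes called in the postnatal set, 92 were called higher in both and 44 lower in both, against 41.8 and 18.2 expected of unrelated lists, and 95 were called in opposite directions, against 57.1 expected. The expected numbers treat every tested gene as equally likely to be called. Opposite calls exceeded them too, so the excess under vehicle does not by itself show that the response recurs. Against the Cre response under UC2288, 63 were higher and 8 lower in both (7.95 and 0.790 expected) and 2 were opposite (5.58 expected). The 303 genes higher in the postnatal set were higher as a list in that comparison (median log2 fold change 0.38, 238 above 0, limma camera adjusted p 0.0172 with estimated correlation). In the vehicle comparison with Cre- they were not (median log2 fold change -0.00, limma camera adjusted p 0.00545 with the preset and 0.464 with the estimated correlation). The genes lower in the postnatal set were lower as a list with the preset correlation but not with the estimated one, both under UC2288 (median log2 fold change -0.40, limma camera adjusted p 5.57e-11 and 0.0966) and under vehicle (-0.26; 0.00468 and 0.443). Across all comparisons, among lists of at least 3 tested genes, 65 of 148 list tests passed with the preset correlation and 30 with the estimated one, and in 17 list tests, none of which passed, the median, mean and test did not share a sign.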

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

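The regroupings of libraries were planned before the data were examined, while the tests of the 3 patterns weighed below were chosen after the result was seen. Within groups, 84 sets of values were screened with Dixon's test, of which about 1 in 20 would exceed the critical value by chance, and 6 did. They were the total of BLZ Jung oil replicate 2 (224692 counts), Cx3cr1 in postnatal Jung tamoxifen replicate 1 (2264 CPM), Cx3cr1 (2047 CPM) and the homeostatic score (10.57) in UC2288 Cre+ replicate 3, the mitochondrial share in postnatal Littman Cre+ replicate 1 (6.69%) and the homeostatic score in adult Littman oil replicate 3 (10.61). Only UC2288 Cre+ replicate 3 exceeded it on 2 measures.

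The effect of UC2288 differed by genotype for 96 genes, a count that ran from 1 (without UC2288 Cre- replicate 1) to 533 (without UC2288 Cre- replicate 3) when single libraries were left out, and was 2 without the libraries that stand apart. The log2 difference was 4.98 for Wdr89, 9.00 for Rpl36-ps3 (a fit to 0 counts in 1 group, which fell to 3.63 with edgeR adjusted p 0.590 without UC2288 Cre+ replicate 4), 3.42 for Sftpa1, 1.88 for Ube2c, 1.54 for Cdk1 and 1.65 for Cst3. It was -2.91 for Pim1, -2.90 for Hipk2, -2.64 for Gtf2ird2 and -2.45 for Map3k3. Except for Wdr89, every one of these calls was lost without some single library.

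The postnatal Littman and Jung effects differed for 25 genes. The log2 difference was 2.07 for Axl, 0.62 for Ctsb, 1.49 for Cdkn1a, 3.98 for Ifitm3, 0.64 for Olfml3, 2.26 for Htra3, 1.02 for Lgals3bp, 1.21 for Ccl12, 0.54 for B2m, 1.07 for H2-K1, 1.39 for Lyz2, 0.74 for H2-D1 and 3.18 for Ifi204. It was -1.14 for Mgll, -1.63 for Sdk1, -1.35 for Cx3cr1 and -1.25 for Slc24a3. The Littman side compares genotypes and the Jung side compares treatments, so the line is not separated from the kind of control.

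Regrouping the libraries asked whether the called counts could arise by chance from these samples. The real grouping called more genes than any other grouping of the reported draw or full set in postnatal Littman (552 against at most 193; 1 of 100 groupings reached it, the real one), postnatal Jung (6 against 5; 1 of 100), the vehicle Cre+ comparisons with Cre- (1347 against 712; 1 of 100) and with oil (1556 against 0; 1 of 35) and UC2288 Cre+ against Cre- (198 against 115; 1 of 56). In the postnatal line difference 1 of 100 drawn groupings reached 25, the real one, with 12 the highest other, but a grouping from another draw called 35, so the real count was not the highest there. In the interaction 2 of 100 reached 96, with 137 the highest other. Chance could not be excluded for adult Littman (1 gene, reached by 11 of 35, at most 29), BLZ-titled Littman (3, reached by 3 of 35, at most 12), UC2288 in Cre+ (36, reached by 6 of 100, at most 264) and UC2288 in Cre- (1, reached by 14 of 56, at most 5). Where edgeR called 0 genes every grouping reached that, and the highest other counts were 484 in adult Jung and 208 in BLZ-titled Jung (35 groupings each), 2 for oil Cre+ against Cre-, 36 in the BLZ-titled and 476 in the adult line difference (100 each). The values of 484, 208 and 476 point to structure among the libraries that the groups do not describe, and drawn groupings depend on the draw. The grouping with 484 only swaps adult Jung oil replicate 4 with tamoxifen replicate 1. That with 208 only swaps BLZ-titled Jung oil replicate 3 with tamoxifen replicate 1. The 0 calls in these 2 sets thus depend on where those libraries are placed, though leaving out any single library kept 0 calls. The grouping with 264 only moves UC2288 Cre+ replicate 1 to the vehicle side, so it points to that library, without which the real groups gave 266.

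Ribosomal protein pseudogenes were higher in UC2288 Cre+ than in vehicle Cre+ (46 of 47 above 0, median log2 fold change 1.03). A fixed share of parent gene reads falling on pseudogenes would give both the same change. The 31 tested parent genes rose too, with a median log2 fold change of 0.53. Pseudogenes exceeded their parents by a median of 0.57 (95% interval 0.45 to 0.65). At 1 common depth the median of the pseudogenes was 1.00 (0.86 to 1.1497). These intervals resample pseudogenes of 1 fit and leave out variation between libraries. The pseudogene share ran from 0.961% to 2.19% in UC2288 Cre+, and 10 of the 47 pseudogenes were called higher. For these libraries only, the median of 0.57 argues against a fixed share of reads as the whole cause. The median of 1.00 argues against depth as the whole cause. A share of reads that varies between libraries was not tested and stays open. Pseudogenes held 0.830 ± 0.101% of counts in vehicle Cre+ with tamoxifen but 1.48 ± 0.125% in Cre-, 1.69 ± 0.286% in oil Cre+ and 1.55 ± 0.525% in UC2288 Cre+, so the vehicle tamoxifen group may be the unusual one. An effect of UC2288 or RNA quality stays open and was not tested.

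Replicate 3 of UC2288 Cre+ stood apart, with P2ry12 at 5085 CPM against 903 to 1272 in the other 4. A mixture with 66.0% of cells like oil Cre+ could give its interferon level, but its homeostatic sum was 1.14 times the highest such mixture (49789 against 43799.6, an excess of 5989 with a group SD of 5130.4). That test replaced a first gene-by-gene bound, which left a mixture possible (score minus bound -0.21), so a mixture stays open. Its interferon score of 6.98 lay 2.24 above the highest library of the groups without an interferon response. This argues against an exchange with a library of those groups. Its homeostatic score of 10.57 lay 1.27 above the highest vehicle Cre+ tamoxifen library. A vehicle Cre+ library with a weak response could lie as far from the rest, so an exchange with that kind stays open. The 2 shallower UC2288 Cre+ libraries lay near the rest, which argues against depth. A weaker response in that sample stays open as a hypothesis that was not tested.

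Plac8 and Itgal, genes on the monocyte list, were higher with the interferon genes in vehicle Cre+ tamoxifen libraries (ratios of pooled counts against Cre- of 24.5 and 19.9, with exact 95% intervals of 12.2 to 57.6 and 6.45 to 99.3 that cover counting error only). Monocytes, which the gate does not remove since it excludes CD206 and Ly6G only, would bring other markers, but the rest of the list had 31 against 24 pooled counts (ratio 1.40), mostly Vim, with Ly6c2 at 0 and 0 and Ccr2 at 3 and 3. Between libraries the log2 difference was 0.46 for that rest (95% interval -0.75 to 1.67) and 3.46 for Plac8 (2.42 to 4.51), a gap of 0.75 that argues against monocytes as the source of Plac8, while for Itgal (1.65 to 3.11) the gap was -0.0170, so monocytes stay open there. At 1 common depth 27 interferon genes were still higher, as were Plac8 (log2 fold change 4.37) and Itgal (3.72, and called in each of the 6 of 10 further draws that kept it for testing), which argues against depth. Induction of both genes in microglia by interferon stays open as a hypothesis and was not tested.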

How the results depend on the processing

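The variations of the analysis were planned, except sex as a covariate, leaving out the libraries that stand apart, leaving out those with neutrophil or erythroid transcripts, and the adult join, which were tests chosen after the result was seen. Libraries that stand apart were chosen partly from the outcome measures. Among comparisons with many calls, the postnatal Littman count ranged from 415 to 589 over the settings and 402 to 636 when single libraries were left out, and vehicle tamoxifen against oil from 1051 to 1773 and 1157 to 1400. No called named gene turned direction in any setting that tested it. Of 233 calls of named genes, 56 were lost without some single library, 28 with limma-voom, 4 with RLE size factors, 4 with DESeq2 and 3 without the low-count filter. Fitting only the compared groups lost 22 of 202, the replicate block 17 of 202, thinning 19 of 211, the sex covariate 12, leaving out libraries with blood transcripts 32 of 166 and those that stand apart 23 of 58. Thinned counts depend on the draw.

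No comparison met the rule for pairing by replicate number, which asked every pair of samples to be correlated (correlations of pairs -0.359 to 0.344). Adult Jung came nearest, with a mean of 0.146 for pairs against -0.0509 for other combinations. Pairing is therefore not shown and not excluded, and values with the replicate block are a check of the model only. Postnatal Jung, 6 genes, gave 15 without the low-count filter, 12 with only the compared groups, 26 with the block and 2 without the libraries with blood transcripts. Leaving out 1 library gave 2 to 8: 2 without oil 1, 3 or 4 or tamoxifen 2 or 4, and 3 without oil 2 or 5. In adult Littman, 1 gene became 10 without the filter, 2 with the block (neither of them Cdkn1a, log2 fold change 1.71, edgeR adjusted p 0.128), 0 with sex as a covariate and 7 without the library that stands apart. Without single libraries the count was 0 to 7: 0 without oil 1 or 2 or tamoxifen 1 or 2, where Cdkn1a had edgeR adjusted p 0.0679, 0.0760, 0.110 and 0.104, 7 without oil 3 and 3 without oil 4. Adult Jung, 0 genes, gave 6 without the filter and 0 to 0 when single libraries were left out.

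BLZ-titled Littman, 3 genes, gave 44 without the low-count filter, 5 with DESeq2, 7 with only the compared groups, 32 with the block, 1 when thinned, 10 with limma-voom, 1 with sex as a covariate and 1 without the libraries with blood transcripts. All 3 oil libraries were male by Xist and 3 of 4 tamoxifen libraries female, so sex and treatment are close to confounded there. The calls for H2-D1 and Cd300lf could reflect sex. Both were lost with sex as a covariate, but only the Cd300lf fold shrank, so the lost H2-D1 call does not show sex as its source. With 1 library removed it was 1 to 13: 1 without oil 2 or 3 or tamoxifen 2, 9 without tamoxifen 1, 13 without tamoxifen 3 and 7 without tamoxifen 4. BLZ-titled Jung stayed at 0 in every setting and at 0 to 0 when single libraries were left out.

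Vehicle tamoxifen Cre+ against Cre-, 1347 genes, gave 865 when thinned, 798 of them shared, and 949 to 1260 when single libraries were left out. Vehicle oil Cre+ against Cre-, 0 genes, gave 1 with RLE size factors, 15 without the filter, 3 with DESeq2, 4 with only the compared groups, 10 with the block, 1 when thinned and 3 with limma-voom. Leaving out 1 library gave 0 to 5: 1 without oil 1, 5 without oil 3, 1 without Cre- 1 and 2 without Cre- 4.

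UC2288 in Cre+, 36 genes, gave 21 with RLE size factors, 132 without the filter, 140 with DESeq2, 2 with only the compared groups, 96 with the block, 19 with limma-voom, 22 with sex as a covariate and 3 without the libraries that stand apart. Without single libraries the count was 1 to 266. UC2288 Cre+ 1, 2, 3, 4 and 5 gave 266, 4, 12, 3 and 101 when left out, and vehicle Cre+ 1, 2 and 3 gave 2, 9 and 1. Effects of UC2288 in Cre+ thus rest on which libraries are kept. UC2288 in Cre-, 1 gene, gave 36 without the filter, 2 with the block, 0 when thinned, 0 with limma-voom, 7 without the library that stands apart and 0 without the libraries with blood transcripts. With 1 library removed it was 0 to 45: 0 without UC2288 Cre- 1, 3 without 2 and 45 without 3. UC2288 Cre+ against Cre-, 198 genes, gave 111 with only the compared groups, 119 with the block and 136 to 274 when single libraries were left out.

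The interaction, 96 genes, gave 179 without the filter, 163 with DESeq2, 33 with only the compared groups, 46 with the block, 349 with limma-voom, 46 with sex as a covariate, 2 without the libraries that stand apart and 1 without those with blood transcripts. With RLE size factors 37 were higher and 55 lower, against 47 and 49. Leaving out 1 library gave 1 to 533. UC2288 Cre+ 1 to 5 gave 380, 27, 41, 20 and 190 when left out, and UC2288 Cre- 1 to 3 gave 1, 14 and 533. Vehicle Cre+ 1 to 4 gave 23, 57, 13 and 27, and vehicle Cre- 1, 2, 3 and 5 gave 11, 23, 20 and 45.

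The postnatal line difference, 25 genes, gave 55 without the filter, 47 with DESeq2 and 48 with limma-voom. Without single libraries the count was 22 to 76, with 38 without Littman Cre+ 1, 76 without Cre+ 2 and 38 without Cre+ 3. The BLZ-titled line difference, 0 genes, gave 10 without the filter, 1 with DESeq2, 1 with the block and 1 with limma-voom, and the adult line difference, 0 genes, gave 12 without the filter and 1 with the block. Both stayed at 0 to 0 when single libraries were left out. The overlap of postnatal and vehicle calls, 136 genes, was 112 with DESeq2 and 160 without the filter. Of 65 list calls on lists of at least 3 tested genes, 30 held with the estimated correlation.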

Other observations

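The tests in this part were chosen after the result was seen, except the leaving out of single libraries and the other variations named, which were planned. The interferon score of BLZ-titled Littman libraries was 7.81 ± 0.186 with oil (n = 3) and 7.71 ± 0.2999 with tamoxifen (n = 4), against 5.00 ± 0.262 and 5.32 ± 0.253 in BLZ-titled Jung libraries (n = 4 and 4). The score was high without tamoxifen, which may be why no interferon gene was called there while Cdkn1a was (1 gene kept when sex was a covariate). Line, sex and the conflicting BLZ945 labels are not separated in that contrast, and it was not tested.

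In the vehicle and UC2288 table the interferon score was 7.94 ± 0.113 in vehicle Cre+ with tamoxifen (n = 4) and 7.77 ± 0.461 in UC2288 Cre+ (n = 5), against 4.49 ± 0.159 in vehicle Cre- (n = 5), 4.47 ± 0.145 in oil Cre+ (n = 4) and 4.43 ± 0.153 in UC2288 Cre- (n = 3). The homeostatic score was 9.24 ± 0.0375 in vehicle Cre+ with tamoxifen, 9.57 ± 0.575 in UC2288 Cre+ (10.57 in replicate 3 and 9.19 to 9.55 in the other 4), 10.23 ± 0.101 in vehicle Cre-, 10.48 ± 0.114 in oil Cre+ and 10.15 ± 0.127 in UC2288 Cre-. The homeostatic scores of oil Cre+ (10.38 to 10.64) and vehicle Cre- (10.08 to 10.35) did not overlap, and no group had neither Cre nor tamoxifen. No change of Cdkn1a mRNA was called with UC2288 (688 ± 133 CPM in UC2288 Cre+ against 826 ± 177 in vehicle Cre+ with tamoxifen). These counts hold no measure of p21 protein, so whether the compound worked stays open.

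The 2 vehicle comparisons share the 4 Cre+ tamoxifen libraries, so their agreement is partly built in. They had 563 genes higher and 533 lower in both and 0 opposite, with 115 and 97.4 expected of independent lists and a correlation of 0.923. In 10 simulated tables without any effect the sharing alone gave a mean correlation of 0.486 and 0.1 genes. Each gene was drawn independently there, without structure shared between genes. The 0.1 therefore does not measure how many shared calls the sharing adds in these libraries. With the shared libraries split between the comparisons in 6 ways, 257 to 302 genes were higher and 168 to 214 lower in both, with correlations of 0.797 to 0.833.

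Transcripts of blood cells were found in some libraries. Neutrophil markers had 511 counts in postnatal Littman Cre- replicate 2, 748 in BLZ-titled Littman oil replicate 3, 679 in BLZ-titled Littman tamoxifen replicate 1 and 166 in UC2288 Cre- replicate 1. Erythroid markers had 369 counts in postnatal Jung oil replicate 1 and 83 in vehicle Cre- replicate 5. The sort excluded Ly6G, which should remove neutrophils, so carry-over of their RNA is possible and was not tested. Without these libraries the Pim1 call was lost and UC2288 in Cre- gave 0 genes. Its log2 fold change was still 1.99 without UC2288 Cre- replicate 1, against 2.47 with it, so the lost call does not show neutrophil RNA as the source of Pim1. That library also stood apart on Fkbp5 and Ddit4, so neutrophil transcripts were not its only difference.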
